A study of Mus musculus with 8 samples.

How the data were processed

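PU.1 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in AML246 cells, a mouse acute myeloid leukaemia line in which doxycycline (Dox) restores the transcription factor PU.1. Per the labels' protocols, cells were grown in IL-3 medium, Dox (0.1 ug/mL) was added at the start of a 24 day course and removed on day 12, and viable cells were sorted before the immunoprecipitation. Libraries were prepared with an Illumina TruSeq kit and sequenced on a NextSeq instrument, per the labels' protocols. 8 samples were labelled, and 7 of them had a file here. The sample labelled as 12 days off Dox was not analysed here.

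Each deposited file was a list of peak summits, with 1 position per called peak. Per the submitters' processing notes, MACS2 was the tool and mm10 the genome build. The deposited score of each summit was read as the −log10 q-value of the peak, because the lowest score in all files was 1.30104 and MACS2's usual q limit of 0.05 corresponds to 1.30103. The aligner, the MACS2 version, the control library, read filters and sequencing depth were not given in the sources used here, and neither was whether peaks were called on single or pooled libraries. Scores therefore were the authors' own per-list values and were used to describe, rank or filter sites. The same score minimums were applied to all lists, so counts at a minimum also depend on depth and control. Scores of a site or gene given for different libraries do not measure a change in binding. A list can be long because of stronger binding, deeper sequencing or a different control, so the number of called sites was not treated as a level of binding. A missing call was not treated as absence of binding.

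Libraries were grouped by title. For the last 3 libraries the title and the treatment label named different time points. The library titled Day 12- 4 was labelled as 12 days of Dox with a sort for Cd11b-high cells. The library titled Day 12- 8 was labelled as 4 days off Dox, and the library titled Day 12- 12 as 8 days off Dox. For the sample labelled as 12 days off Dox the title gave no time point. By treatment label the samples ran from 0 to 12 days of Dox and then from 4 to 12 days off it. The titles were used throughout. The treatment labels were tried as an alternative reading only for the counts of sites called in no withdrawal library and in withdrawal libraries alone.

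Files were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. A site was counted as shared when a summit of the other list lay within 100 bp. Chance sharing was the mean of 100 circular shifts of the summits within each chromosome. For site classes the 7 lists were merged by single linkage at 100 bp, and each merged site was classed by the libraries that called it. Because linkage can chain through another library, class counts can exceed pairwise counts. The smallest distance between summits of one list was 131 bp. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only and say nothing of the spread between cultures. To compare lists of different length, each list was also reduced to its 8043 highest-scoring sites, the length of the shortest list.

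Genes were taken from a RefSeq gene table for GRCm38.p6, whose coordinates are those of mm10, with 21887 protein-coding genes. The table gave no strand, exons or transcription start sites. The planned promoter share was therefore replaced by the share of sites within 1 kb of either end of a protein-coding gene, and sites were not assigned to exons or introns. The nearest gene of a site was the protein-coding gene at the smallest distance from its body. No genome sequence was used here, so the planned share of sites with a PU.1-type motif was not computed.

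10 gene lists holding 190 genes, all matched in the table, covered myeloid maturation, myeloid transcription factors, stem and leukaemia-associated genes, B-lymphoid, T-lymphoid, erythroid and megakaryocytic, mast cell and basophil, cell cycle, housekeeping and non-haematopoietic genes. A gene had a site when a summit lay in its body or within 10 kb on either side. The score given for a gene was that of its highest-scoring site in this window, which can lie outside the gene or nearer to another gene. For each library the share of a list with a site was given as a percentile among 10000 random lists of protein-coding genes matched on gene length. For myeloid maturation, cell cycle and housekeeping genes the median of the genes' highest scores was also placed among them. The percentile describes that library and is not a test between conditions. Sites on unplaced scaffolds were counted in the list totals and left out of gene comparisons.

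The groups, gene lists and rule for named genes were chosen before the data were examined. So were the distances and alternatives, except sharing within 2 kb and leaving out each library titled knockdown. Named genes were the 4 genes of each list with the highest-scoring day 12 site, and, for the myeloid and stem lists, up to 8 genes with a site at day 12 and none at day 0. Named sites were the 10 highest-scoring day 12 sites with no day 0 summit within 500 bp and the 10 highest-scoring day 12 sites called in all 7 libraries. The 5 highest-scoring sites of day 0 and of each library titled knockdown with no day 12 summit within 500 bp were also named. Sites within 10 kb of a listed site were skipped. Sites on main chromosomes were not filtered for repeats or other regions prone to background signal, so named sites can include such background. Spi1, Itgam and Csf1r were always named. A few further genes are named as chosen after their values were seen, and some genes that the rule takes are not reported here.

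Alternatives were score minimums of 5, 10 and 20, the lists of equal length, other sharing distances, other windows around genes and gene ends, main chromosomes only, and the treatment labels in place of the titles. The procedures were tested on simulated data. With 5, 20 and 50% of 8000 simulated sites placed at day 12 sites, 5.73, 20.4 and 50.3% were recovered as shared, with 5.67, 20.6 and 50.4% due once chance sharing was added. With 30% of 10000 simulated sites placed near gene ends, 32.3% were recovered, on a background of 2.74%. A list with a simulated site at every gene reached a percentile of 100, and 5% of 100 lists with none placed lay above the 95th percentile. Those sites lay at random over the genome, and the lists with none placed were drawn at random from the same genes. The check therefore does not cover chosen gene lists or sites that gather at gene ends.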

Results

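PU.1 is an ETS-family transcription factor that drives myeloid differentiation, and the time course followed its binding sites as PU.1 was restored with Dox and then reduced by Dox withdrawal. The restoration series held 4 libraries, at day 0 (untreated) and after 4, 8 and 12 days of Dox. The withdrawal series held 3 libraries, titled knockdown Day 12- 4, Day 12- 8 and Day 12- 12. Their treatment labels named other time points, and the library titled Day 12- 4 was labelled as a Cd11b-high sort after 12 days of Dox, so each of the 3 is called by its title. By title every time point had 1 library, so no difference between time points could be set against replicate error and no p-values are given. By treatment label 12 days of Dox had 2 libraries, with 86271 and 9868 sites, which differed in the sorted cells and so were not replicates. Sequencing depth was unknown, and values in the text describe these libraries.

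The gene encoding PU.1 itself, Spi1 (chromosome 2, 91082374 to 91115759, mm10), carried called sites in all 7 libraries. A site 11.7 kb outside the lower coordinate of the gene (91070593 to 91070711) was called in every library, with scores of 112 at day 0, 340.1 at day 4, 349 at day 8 and 534 at day 12. The same site scored 391, 480.1 and 485 in the libraries titled Day 12- 4, Day 12- 8 and Day 12- 12. Another site, 0.712 kb inside the gene (91083075 to 91083096), was also called in all 7, with scores of 16.1 at day 0 and 674 at day 12. A further site, 2.37 kb inside the gene (91084724 to 91084773), scored 374 at day 12 and was called in 5 libraries, with no call at day 0 or in the library titled Day 12- 8. Around Spi1, 3 sites lay within 10 kb at day 0 and 12 at day 12. Scores belong to each list and depend on its depth and control, so they do not measure a change in binding at these positions.

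Itgam (chromosome 7, 128062640 to 128118491), which encodes the CD11b integrin chain used to sort myeloid cells, had no called site within 10 kb at day 0. It had 8 sites at day 4, 3 at day 8 and 7 at day 12. In the withdrawal series it had 1 site in the library titled Day 12- 4, 0 in Day 12- 8 and 5 in Day 12- 12. Csf1r (chromosome 18, 61105572 to 61131139), the receptor for macrophage colony-stimulating factor, had 0 sites at day 0, then 6, 5 and 10 at days 4, 8 and 12. Its highest-scoring day 12 site (61105879 to 61105967), inside the gene, scored 307 at day 12, 118 at day 4 and 25.4 at day 8. That site was also called in the library titled Day 12- 12, at a score of 6.20, and in neither of the other 2 withdrawal libraries. Csf1r had 1, 3 and 17 sites in the libraries titled Day 12- 4, Day 12- 8 and Day 12- 12, and another site inside it (61108624 to 61108788) was called in all 3.

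**Figure D1:**
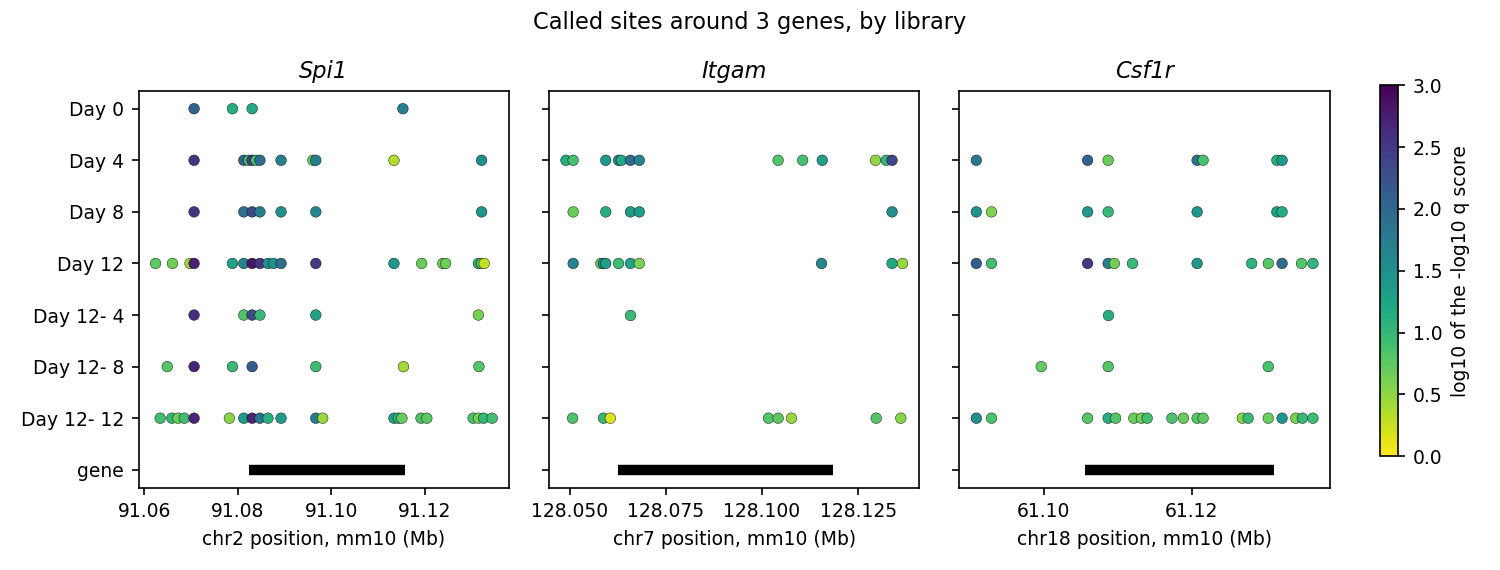
Called sites around Spi1, Itgam and Csf1r. The horizontal axis is the mm10 position in Mb, each line of points is 1 library, colour gives the log10 of the −log10 q score, and the black bar is the gene body; Itgam and Csf1r have no day 0 site within 10 kb, while Spi1 has 3.

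The restoration series asked where PU.1 bound as its level was restored. The day 0 list held 8043 called sites, and the lists at days 4, 8 and 12 held 57424, 33962 and 86271. The day 12 list was thus 10.7 times as long as the day 0 list, and the lists at days 4 and 8 were 7.14 and 4.22 times as long. The order was not steady in time, since the day 8 list was shorter than the day 4 list. Counting only sites with a score of at least 20, the 4 libraries held 1286, 19689, 13128 and 21164 sites.

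**Figure D2:**
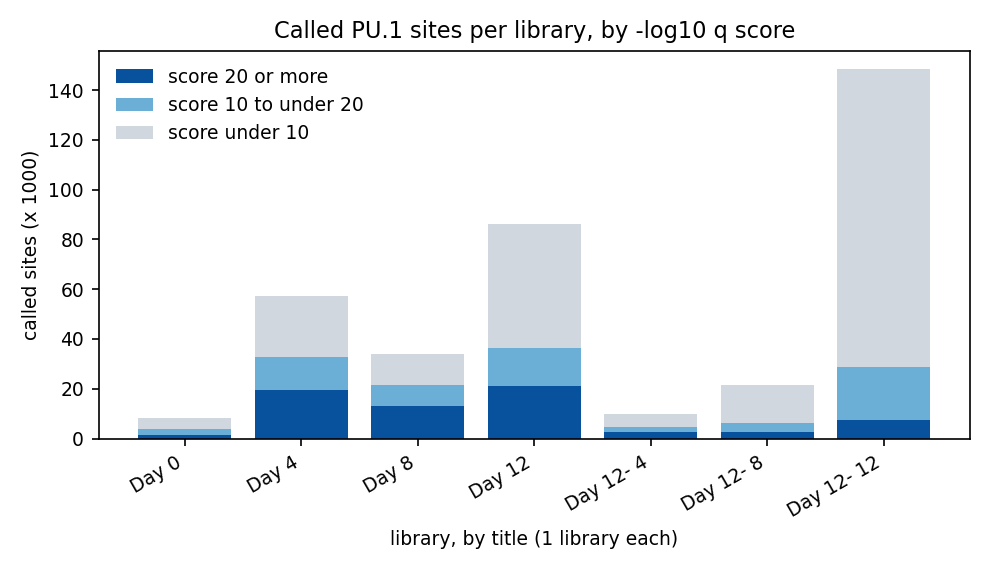
Called PU.1 sites per library (vertical axis, number of sites divided by 1000), split by −log10 q score. Each bar is 1 library; the library titled Day 12- 12 has the most sites, 148415, of which 7615 score 20 or more, and day 12 has 86271, of which 21164 do.

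Of the merged sites, 83055 were called at day 12 and not at day 0, and 3216 were called at both times. With 8043 day 0 sites against 86271 at day 12, most day 12 sites had to lack a day 0 call whatever the binding. Among lists of 8043 sites, 6244 merged sites were called at day 12 and not at day 0. The 10 highest-scoring day 12 sites with no day 0 summit within 500 bp lay in or near Cyth4, Adcy7, Ptpn1, Zc3h12a, Prune1, Ski, Ptk2, Rac2, Arhgef10l and Epas1. The first lay inside Cyth4, an activator of ARF GTPases, at position 78599322 of chromosome 15, and scored 859 at day 12, 495 at day 4 and 416 at day 8. The site inside Rac2, a small GTPase of blood cells, at position 78571784 of chromosome 15, scored 807 at day 12 and lay 999 bp from a gene end. The site 256 bp from Zc3h12a, an RNase that limits inflammatory transcripts (chromosome 4, 125118158), scored 844 at day 12. All 10 were called at days 4 and 8, with scores from 161 near Arhgef10l to 495 near Cyth4 at day 4.

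Of the 8043 day 0 sites, 33.4% (95% interval 32.3 to 34.4) had a day 12 summit within 100 bp, against 0.824% after shifting positions. The share was 16.3% (15.5 to 17.1) with day 4 and 37.9% (36.9 to 39.0) with day 8. Of the day 8 sites, 73.3% (72.8 to 73.7) were shared with day 4 and 58.8% (58.3 to 59.4) with day 12. The highest-scoring day 0 sites with no day 12 summit within 500 bp were nearest to Esp38, Elf2, Ankrd44, Pabpc1 and Malt1. The site nearest to Esp38 lay 102 kb from that gene, and sites were not filtered here for repeats. The site inside Elf2, another ETS-family gene (chromosome 3, 51277539), scored 105 at day 0. The site inside Malt1, a signalling protease of lymphocytes (chromosome 18, 65431065), scored 56.1 at day 0 and 147 at day 8, and the nearest day 12 summit lay 506 bp away. Each peak had 1 summit, so a broad peak can hide a neighbour. Of 3430 day 0 sites with no day 12 summit within 500 bp, 1072 (31.3%) had one within 2 kb.

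Sites called in all 7 libraries numbered 936. The highest-scoring of these at day 12 lay in or near Cbfa2t3, Cmklr1, Ptgr2, Soga1, Tbc1d22a, Calhm2, Pisd, Rasa3, Serpinf1 and Fosb. The first, 1393 bp outside Cbfa2t3, a transcriptional co-repressor of blood progenitors (chromosome 8, 122700725), scored 904 at day 12 and 30.1 at day 0. The site inside Cmklr1, the chemerin receptor (chromosome 5, 113644656), scored 894 at day 12 and 45.4 at day 0. The site inside Rasa3, a Ras GTPase-activating protein (chromosome 8, 13594988), scored 842 at day 12 and 106 at day 0.

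**Figure D3:**
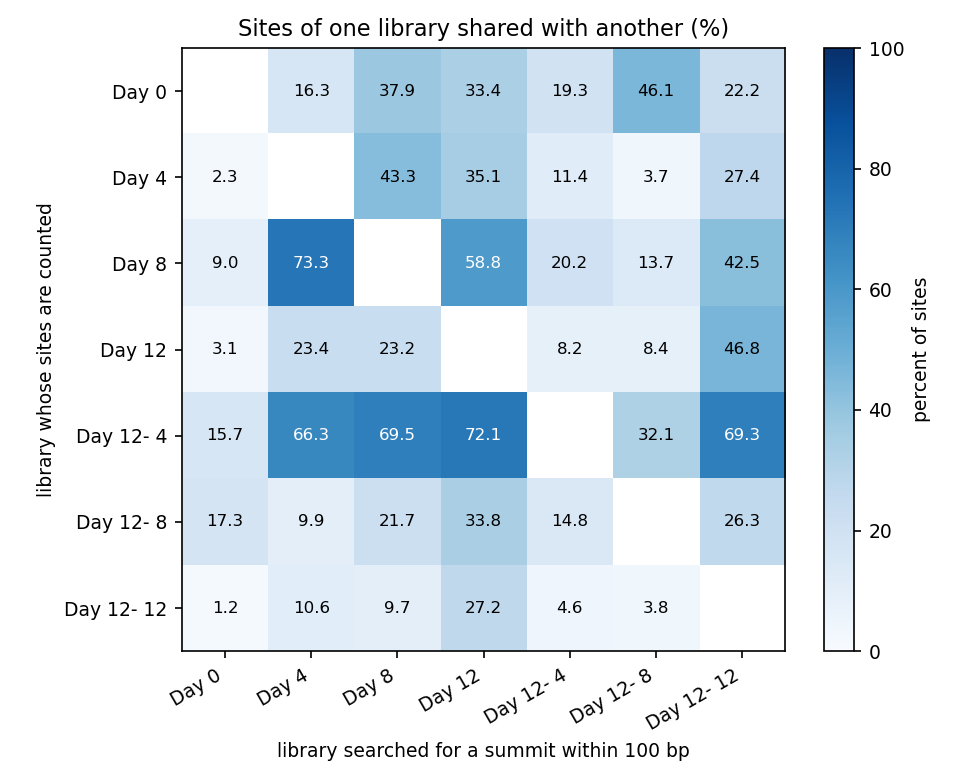
Percent of the sites of each library (lines) with a summit of another library (columns) within 100 bp. Each cell is 1 ordered pair of libraries; 72.1% of sites of the library titled Day 12- 4 are shared with day 12, and 46.1% of day 0 sites with the library titled Day 12- 8.

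Where the sites lay relative to genes differed between the lists. At day 0, 61.8% (60.8 to 62.9) of sites were within 1 kb of an end of a protein-coding gene. The share was 12.0% (11.7 to 12.2) at day 4, 21.6% (21.1 to 22.0) at day 8 and 17.8% (17.5 to 18.0) at day 12, against 3.18 to 3.25% for shifted positions. Sites called at both day 0 and day 12 were near gene ends in 63.8% (62.1 to 65.5) of cases, and those called at day 12 and not day 0 in 16.0% (15.8 to 16.3). Among the 936 sites called in all 7 libraries the share was 75.2% (72.3 to 78.0). Among the 8043 highest-scoring sites of each list the share was 46.8% (45.7 to 47.9) at day 12 and 16.2% (15.4 to 17.0) at day 4. The gene table has no strand, so both ends of each gene counted.

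**Figure D4:**
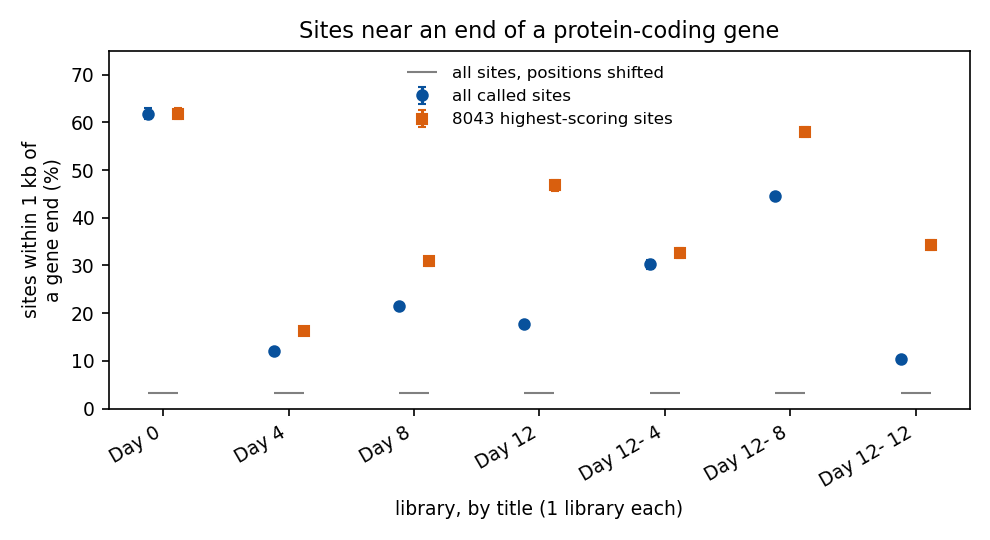
Percent of sites within 1 kb of either end of a protein-coding gene, per library. Circles are all called sites, squares the 8043 highest-scoring sites, bars exact 95% binomial intervals (counting error only) and grey dashes shifted positions; day 0 lies at 61.8% and day 4 at 12.0%.

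Genes of myeloid maturation, which encode receptors, granule proteins and the phagocyte oxidase, had a site in 11 of 37 cases at day 0 and in 35 of 37 at day 12. The counts at days 4 and 8 were 36 and 32. All 11 genes with a day 0 site also had a day 12 site, and 24 genes had a site at day 12 and none at day 0. Subunits of the phagocyte NADPH oxidase were among the highest, with day 12 scores of 765 at Ncf4, 666 at Ncf1 and 485 at Cyba, and day 0 scores of 5.36, 8.30 and 19.6. Cd300a, an inhibitory receptor, scored 778 at day 12 and 16.4 at day 0. Cd68, a lysosomal glycoprotein of macrophages, Pirb, an inhibitory immunoglobulin-like receptor, and Elane, neutrophil elastase, had no day 0 site and scored 428, 198 and 169 at day 12. The Elane value came from a site outside that gene (chromosome 10, 79879576). That site lay closer to Prtn3 (79879667 to 79883174), a granule protease gene with a day 0 score of 8.57, than to Elane (79886312 to 79888216). The Cd68 site (chromosome 11, 69672544) also lay outside its gene, which ends at 69666170. The Ncf1 and Pirb sites lay outside their genes too. Cd14, the lipopolysaccharide co-receptor, Csf3r, the receptor for granulocyte colony-stimulating factor, and Fcgr1, a high-affinity IgG receptor, also lacked a day 0 site and scored 162, 94.3 and 76.5 at day 12. The Cd14 site (chromosome 18, 36735359) and the Fcgr1 site (chromosome 3, 96278248) lay outside those genes, and the Csf3r site lay inside. The 2 genes with no day 12 site, named after their values were seen, were Clec7a, with none in any library, and S100a9, with 3 sites at day 4 and 2 at day 8.

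Set against random lists matched on gene length, the share of myeloid maturation genes with a site lay at the 24.3 percentile at day 0. It lay above all 10000 random lists at day 4, and at the 99.95 and 99.8 percentiles at days 8 and 12. The median of the genes' highest scores lay above all random lists at days 4 and 8. At day 12 that median was 54.2, only at the 79.2 percentile, while those of cell cycle and housekeeping genes lay at 99.6 and 99. Among lists of 8043 sites the counts were 24, 21 and 16 of 37 at days 4, 8 and 12. The share then lay above all random lists at day 4 and at the 99.995 and 82.2 percentiles at days 8 and 12. Non-haematopoietic genes, such as those for muscle or liver proteins, had a site in 3 of 20 cases at day 0 and 16 of 20 at day 12, at the 56.1 percentile, and in 1 of 20 with the shorter list. High percentiles at day 12 were not particular to myeloid genes, since T-lymphoid, cell cycle and housekeeping genes lay at 97.7, 98.6 and 98.7. Among lists of 8043 sites T-lymphoid genes fell to 45.0, while cell cycle and housekeeping genes lay at 99.91 and 99.36, above myeloid maturation. At day 4 cell cycle and housekeeping genes lay at 80.1 and 94.2 in such lists, below myeloid maturation.

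Myeloid transcription factor genes already had a site in 17 of 23 cases at day 0, above all random lists, and in 21 of 23 at each of days 4, 8 and 12. Housekeeping genes also lay high at day 0, at the 98.6 percentile. Among lists of 8043 sites the counts at days 4, 8 and 12 were 9, 13 and 14 of 23, below that at day 0, and the percentiles were 96.1, 99.9 and 99.3. 6 genes had a site at day 12 and none at day 0. Among them were Fos, Cebpe, a granulocytic factor, Stat3, Id2 and Gfi1, with day 12 scores of 431, 408, 165, 163 and 146. Spi1 and Egr1, the latter a factor of monocytic differentiation, had sites at both times, and Egr1 scored 567 at day 12 and 10.7 at day 0. Klf4 and Maf, named after their values were seen, had sites at day 0 (2 and 1) and none at days 4, 8 or 12. In the withdrawal series Klf4 had 0, 4 and 1 sites and Maf 0, 1 and 2, in title order.

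Stem and leukaemia-associated genes had a site in 17 of 24 cases at day 0, 20 at day 4, 19 at day 8 and 23 at day 12. The percentile among random lists was 99.01 at day 0 and 91.54 at day 12. Among lists of 8043 sites the direction turned, with 8, 9 and 8 of 24 at days 4, 8 and 12 and a day 12 percentile of 47.2. Runx1, Etv6, Ikzf1 and Fli1, all transcription factor genes of blood formation, had the highest day 12 scores, at 558, 308, 247 and 215. 6 genes had a site at day 12 and none at day 0. Bmi1, Myb, Myc and Ikzf2 scored 92.9, 71.9, 34.3 and 16.6 at day 12, Kit, the stem cell factor receptor, scored 12.2, and Mycn scored 3.17. Cd34, named after its values were seen, was the gene with no day 12 site, and had 3 sites at day 4 and 1 at day 8.

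**Figure D5:**
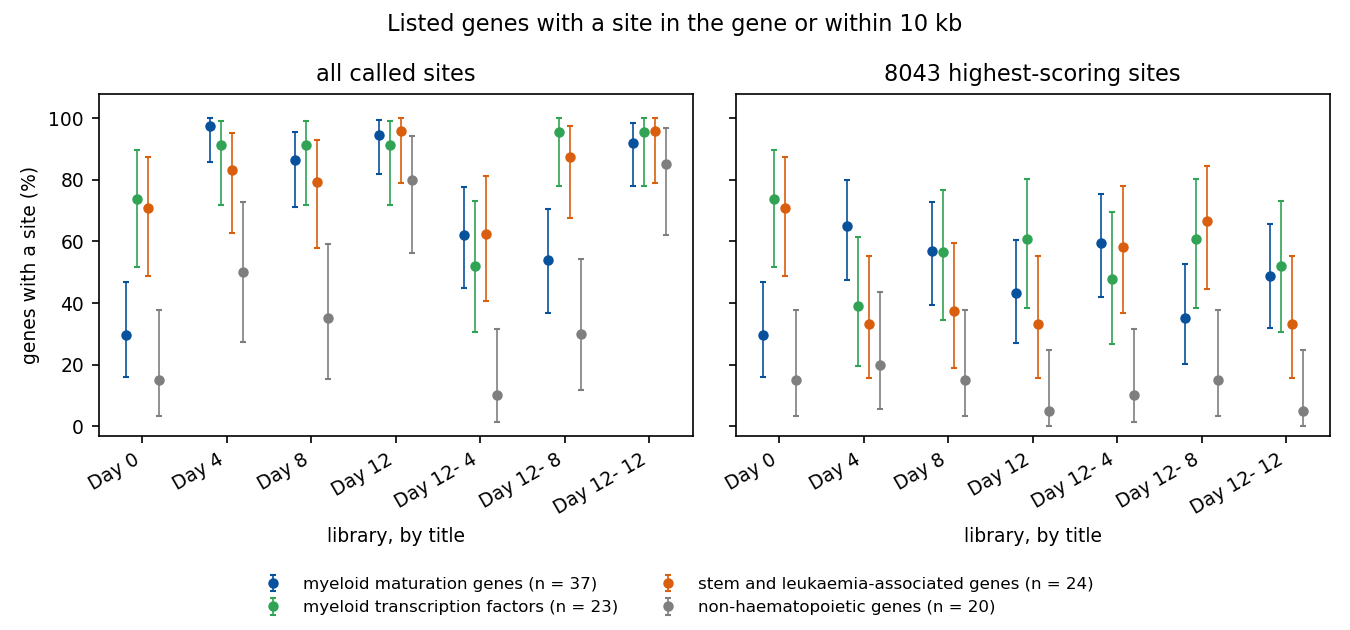
Percent of genes of 4 lists with a site in the gene or within 10 kb, per library, with exact 95% binomial intervals (counting error only). The left panel uses all called sites and the right panel the 8043 highest-scoring sites of each library; on the left, 11 of 37 myeloid maturation genes have a site at day 0 and 35 of 37 at day 12.

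The withdrawal series asked which sites were still called once Dox had been removed. The libraries titled Day 12- 4, Day 12- 8 and Day 12- 12 held 9868, 21377 and 148415 sites, which is 1.23, 2.66 and 18.5 times the day 0 count. At a score of at least 20 they held 2432, 2426 and 7615, so the longest list ranked first of 7 in all sites and 4 of 7 at that score. Of sites in the library titled Day 12- 4, 72.1% (71.2 to 73.0) were shared with day 12. The share was 33.8% (33.2 to 34.4) for Day 12- 8 and 27.2% (27.0 to 27.4) for Day 12- 12. Among lists of 8043 sites the shares were 49.2% (48.1 to 50.3), 32.3% (31.3 to 33.4) and 65.1% (64.0 to 66.1), so the order differed between the full lists and the highest-scoring sites.

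Of the 83055 sites called at day 12 and not day 0, 5975 (7.19%) were called in the library titled Day 12- 4, 5543 (6.67%) in Day 12- 8 and 39072 (47.0%) in Day 12- 12. A further 41117 (49.5%) were called in none of the 3, and this count was 73306 without the library titled Day 12- 12. List length limits these shares, since the libraries titled Day 12- 4 and Day 12- 8 held only 9868 and 21377 sites. Among lists of 8043 sites, 6244 were called at day 12 and not day 0. Of these, 2758 were called in Day 12- 4, 1414 in Day 12- 8 and 4017 in Day 12- 12. The sites near Cyth4, Prune1, Ski, Ptk2, Rac2, Arhgef10l and Epas1 were called in all 3 withdrawal libraries. Those near Adcy7, Ptpn1 and Zc3h12a were called in the libraries titled Day 12- 4 and Day 12- 12 and not in Day 12- 8. At Epas1, a hypoxia-inducible factor gene whose site lay 21.5 kb outside the gene (chromosome 17, 86732328), the scores were 214, 98.9 and 379 in title order. At Cyth4 they were 9.48, 7.54 and 137. Sites called in a withdrawal library and in no restoration library numbered 115290, and 12854 without the library titled Day 12- 12.

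The highest-scoring sites with no day 12 summit within 500 bp were nearest to Phf12, Gm20783, Slc43a2, Arid1b and Kcnrg for the library titled Day 12- 4. For Day 12- 8 they were nearest to Alkbh8, Cfl1, Kcnrg, Tpm3 and Trmt2a, and for Day 12- 12 to Ube2v1, Oard1, Slc8b1, Zbtb5 and Clta. Some of these genes were far away, with the sites nearest to Arid1b, Alkbh8 and Kcnrg lying 367.9, 333.9 and 68.6 kb from them. The Kcnrg entries of Day 12- 4 and Day 12- 8 (chromosome 14, 61681403 and 61681457) were a shared site, also called at days 4 and 8. The site inside Cfl1, which encodes the actin-severing protein cofilin (chromosome 19, 5490502), scored 107 in the library titled Day 12- 8, 54.3 at day 4, 44.8 in Day 12- 4 and 98.1 in Day 12- 12. The site 18.1 kb outside Ube2v1 (chromosome 2, 167589507) scored 170.3 in the library titled Day 12- 12 and was called in no restoration library. The nearest day 12 summit lay between 545 and 1782 bp away for all of these sites except that nearest Arid1b, for which it lay 33482 bp away.

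In the full lists, day 0 sites were shared with the library titled Day 12- 8 in 46.1% (45.0 to 47.2) of cases, against 33.4% (32.3 to 34.4) with day 12. The order turned with score minimums in both lists, at 45.1% with Day 12- 8 and 46.3% with day 12 for at least 10, and at 67.9 and 76.0% for at least 20. Those lists differed in length, with 6428 sites in Day 12- 8 and 36212 at day 12 for at least 10, and 2426 and 21164 for at least 20. The full-list shares were 19.3% (18.4 to 20.1) with Day 12- 4 and 22.2% (21.3 to 23.1) with Day 12- 12. With lists of 8043 sites they were 28.5% (27.5 to 29.5), 18.8% (17.9 to 19.6) and 14.8% (14.1 to 15.6) for Day 12- 8, Day 12- 4 and Day 12- 12. The share of sites within 1 kb of a gene end was 44.6% (43.9 to 45.2) in Day 12- 8, 30.3% (29.3 to 31.2) in Day 12- 4 and 10.3% (10.2 to 10.5) in Day 12- 12.

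Myeloid maturation genes had a site in 23, 20 and 34 of 37 cases in the libraries titled Day 12- 4, Day 12- 8 and Day 12- 12, at the 99.97, 16.1 and 96.8 percentiles of random lists. Of the 24 genes with a site at day 12 and not day 0, 13, 11 and 23 had one in these libraries. Pirb had no site in Day 12- 8, while Elane had 2, 4 and 16 sites in title order. Myeloid transcription factor genes had a site in 12, 22 and 22 of 23 cases, and stem and leukaemia-associated genes in 15, 21 and 23 of 24. Stat3 had no site in the library titled Day 12- 4, and Cebpe had none in Day 12- 8. Non-haematopoietic genes had a site in 2, 6 and 17 of 20 cases. In the library titled Day 12- 8 the myeloid transcription factor list lay at the 99.995 percentile, cell cycle genes at 99.86, housekeeping genes at 99.27 and the non-haematopoietic list at 0.125.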

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

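The check of unplaced scaffolds was chosen only after the lists had been examined. Sites on unplaced scaffolds were outside the gene comparisons, and on 1 scaffold the share of sites in a treated library had a 95% interval wholly above that of the untreated library. In the library titled Day 12- 4, 50 of 9868 sites (0.507%, exact 95% interval 0.376 to 0.667) lay on the scaffold Un_JH584304, against 5 of 8043 (0.0622%, upper bound 0.145) at day 0. The counts at days 4, 8 and 12 were 49, 46 and 32, and those in the libraries titled Day 12- 8 and Day 12- 12 were 4 and 39. Other scaffolds went the other way, such as Un_GL456383 with 22 of 8043 sites at day 0 and 12 of 86271 at day 12. Over all scaffolds, day 0 had the highest share of the 7 libraries, 86 of 8043 sites. No explanation was tested for these values.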

How the results depend on the processing

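Sharing within 2 kb and leaving out each library titled knockdown were chosen only after the data were seen; the other alternatives were planned. No paired analysis was possible because each time point had 1 library by title and the labels gave no replicate numbers shared between groups. The share of sites with a PU.1-type motif and its alternatives were not run, since no genome sequence was used here. Most values changed with a score minimum of 20. Raising the minimum lowers counts by construction, and the cause was not tested for shares or for the other changes. Sequencing depth was unknown and limits every comparison of list lengths. Values follow the order day 0, day 4, day 8, day 12, Day 12- 4, Day 12- 8 and Day 12- 12 where 7 are given.

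Called sites on the main chromosomes alone stayed within 1.5 times of the full counts in all 7 libraries. With a score of at least 5 the library titled Day 12- 12 held 95894 sites. With a score of at least 10 the counts were 3783, 32682, 21686, 36212, 4666, 6428 and 28751, and with at least 20 they were 1286, 19689, 13128, 21164, 2432, 2426 and 7615. Day 12 then held the most sites at both minimums, in place of Day 12- 12, and day 0 the fewest.

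The share of sites near a gene end, with a score of at least 5, was 12.4% at day 4, 19.7% at day 12 and 32.6, 47.3 and 11.6% in Day 12- 4, Day 12- 8 and Day 12- 12. With at least 10 the shares were 63.9, 13.9, 25.3, 27.2, 39.5, 61.8 and 18.6%, and with at least 20 they were 67.7, 15.4, 28.7, 35.8, 43.9, 74.7 and 34.9%, so that Day 12- 8 passed day 0. In lists of 8043 sites the shares from day 4 on were 16.2, 30.8, 46.8, 32.6, 58.0 and 34.2%. Within 500 bp of a gene end they were 49.5, 8.20, 16.8, 12.7, 25.3, 36.1 and 6.62%, and within 2 kb 70.5, 17.6, 27.6, 24.8, 36.8, 53.0 and 16.3%. Day 0 had the highest share under all of these except the score of at least 20.

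The shares of sites with a day 12 summit nearby follow in the order day 0, Day 12- 4, Day 12- 8 and Day 12- 12. With scores of at least 5 in both lists they were 35.2, 77.7, 37.0 and 30.5%, with at least 10 they were 46.3, 86.8, 55.6 and 45.9%, and with at least 20 they were 76.0, 91.2, 79.8 and 85.1%. In lists of 8043 sites they were 19.0, 49.2, 32.3 and 65.1%. Within 50 bp they were 22.5, 54.5, 21.6 and 18.7%, within 250 bp 48.6, 83.5, 49.0 and 35.5%, within 500 bp 57.4, 87.1, 57.2 and 40.1%, and within 2 kb 70.7, 92.2, 70.6 and 58.4%. Day 12- 4 had the highest share under all of these except the lists of 8043 sites, where Day 12- 12 had it.

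Sites called at day 12 and not at day 0 numbered 34184 and 20070 with scores of at least 10 and 20, and 6244 in lists of 8043 sites. Of these, 20844, 13750 and 1629 were called in no library titled knockdown, and this count was 21167 when sites within 500 bp were merged. Sites of the libraries titled knockdown alone numbered 72138, 16637 and 1000 with scores of at least 5, 10 and 20, and 7546 in lists of 8043 sites. Sites called in all 7 libraries numbered 408 with a score of at least 20 and 346 in lists of 8043 sites. Without the library titled Day 12- 12, 73306 sites were called at day 12, not at day 0 and in neither other library titled knockdown, and 12854 sites belonged to those libraries alone. With the treatment labels in place of the titles, the counts called in no withdrawal library and in withdrawal libraries alone were 41895 and 113809, within 1.5 times of the reported values. That reading moved only the library titled Day 12- 4, with 9868 sites, so these counts could change little. The other results were not repeated under the treatment labels.

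The share of myeloid maturation genes with a site, with a score of at least 10, was 32.4 and 67.6% in Day 12- 8 and Day 12- 12. With a score of at least 20 it was 5.41% at day 0, 83.8% at day 4, 62.2% at day 12 and 32.4, 10.8 and 48.6% in the libraries titled knockdown. In lists of 8043 sites it was 64.9, 56.8 and 43.2% at days 4, 8 and 12 and 35.1 and 48.6% in Day 12- 8 and Day 12- 12. Within 2 kb of the gene it was 32.4% in Day 12- 8. Within 50 kb it was 48.6, 100, 97.3 and 100% over restoration and 86.5 and 100% in Day 12- 4 and Day 12- 12. Day 12 exceeded day 0 under all of these alternatives. Its longer list made this likely, since the median of the matched random lists also went from 35.1% at day 0 to 78.4% at day 12. At equal list length the shares were 29.7% (15.9 to 47.0) at day 0 and 43.2% (27.1 to 60.5) at day 12, with overlapping intervals. Among the other 9 gene lists, 143 of 378 alternative values left their 95% interval, 34 upward and 109 downward. For the other pairs of libraries, 46 of 48 shares did so, 34 upward and 12 downward.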

Other observations

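The tests of explanations for the long list of the library titled Day 12- 12 and for the sharing of day 0 sites were chosen only after the result was seen, although the score minimum and the lists of equal length that some of them use were planned.

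B-lymphoid genes had a site in 4 of 15 cases at day 0, 14 at day 4, 13 at day 8 and 11 at day 12, and in 9, 6 and 12 cases in the libraries titled Day 12- 4, Day 12- 8 and Day 12- 12. Btk, a kinase also used by myeloid cells, had the highest day 12 score of the list, 768, and Cd79a scored 166. Igll1 and Vpreb1 shared 1 site, which scored 124. T-lymphoid genes had a site in 3 of 15 cases at day 0 and 14, 12 and 15 at days 4, 8 and 12, then 5, 7 and 15. Cd5 scored 278 at day 12 and Lck 116, and Cd3d and Cd3g shared 1 site that scored 97.3. Erythroid and megakaryocytic genes had a site in 3, 11, 9 and 13 of 15 cases over restoration and in 4, 8 and 14 in the libraries titled knockdown. Gp9, Klf1, Tfrc and Ank1 scored 251, 225, 175 and 119 at day 12. The Gp9 site (chromosome 6, 87789396), the Klf1 site (chromosome 8, 84908674) and the Tfrc site lay outside those genes, and the Ank1 site lay inside.

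Mast cell and basophil genes had a site in 0 of 10 cases at day 0, 7 at day 4, 5 at day 8 and 5 at day 12, then in 1, 1 and 5. The day 12 share lay at the 2.07 percentile of random lists of matched gene length. Hdc, the enzyme of histamine synthesis, scored 459 at day 12, and Tpsb2, Mitf and Il1rl1 scored 33.40, 29.95 and 23.86. Cell cycle genes had a site in 7 of 17 cases at day 0 and 16, 15 and 17 at days 4, 8 and 12, then 13, 16 and 16. Their share lay at the 99.94 percentile in the library titled Day 12- 4. E2f1, Ccnd3, Mki67 and Mcm2 scored 464, 335, 283 and 271 at day 12. In the library titled Day 12- 4 these genes scored 6.14, 17.7, 83.8 and 12.2. Housekeeping genes had a site in 9 of 14 cases at day 0 and 13, 13 and 14 at days 4, 8 and 12, then 9, 13 and 13. Actb, Ywhaz and Tbp scored 471, 380.3 and 311 at day 12. Apoa1, an apolipoprotein of liver and gut, had the highest day 12 score of the non-haematopoietic list, 357, and Gfap and Nphs1 scored 55.8 and 35.0.

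The library titled Day 12- 12 held the most called sites, 148415, although it is titled and labelled as a withdrawal library. Of its 29683 lowest-scoring sites, 20% of the list, 11.6% (11.3 to 12.0) lay within 100 bp of a day 12 site. The mean of 100 circular shifts was 0.804% and the highest value 1.11%, which argues against randomly placed noise as the source of all of them. Shifted positions do not model background that recurs at the same places, so such background stays open. Noise of either kind stays open for most of these sites, since 14.9% (14.5 to 15.3) lay near a site of any other library, against 1.40% in shifts. Of the whole list, 69.0% (102436 sites) was called in no other library. A deeper library or a different control could also let weak sites pass, and at a score of at least 20 the library held 7615 sites and ranked 4 of 7. Depth and control were unknown, so these cannot be told apart, and PU.1 binding that persisted after withdrawal stays open as an untested hypothesis.

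In the full lists and those of equal length, day 0 sites were shared more often with the library titled Day 12- 8 than with any other, and a return of binding toward the untreated state is a candidate explanation. The order against day 12 turned with scores of at least 10 in both lists, at 45.1% for Day 12- 8 and 46.3% for day 12, and with at least 20, at 67.9 and 76.0%. At these minimums Day 12- 8 held 6428 and 2426 sites and day 12 held 36212 and 21164, so the turned order compares lists of unlike length. With lists of equal length the shares were 28.5% (27.5 to 29.5) for Day 12- 8, 14.8% (14.1 to 15.6) for Day 12- 12, 19.0% (18.1 to 19.8) for day 12 and 25.1% (24.2 to 26.1) for day 8. There was no spread between libraries to set these against, so a return stays open for the libraries titled Day 12- 8 and Day 12- 12. It was not tested for Day 12- 4, where the share was 18.8% (17.9 to 19.6). Background that recurs in some libraries was examined through scaffold sites. Of these, 17 were called in exactly day 0, day 8, day 12 and Day 12- 8, and the next highest of the 35 sets of 4 libraries had 8. In the full lists such sites also count toward the shares of day 8 and day 12, so they alone do not raise Day 12- 8 above those. In lists of equal length this need not hold. The set of those 4 libraries held 649 sites in all, and 80.1% of those on chromosomes lay within 1 kb of a gene end. Sites called in day 0 and Day 12- 8 alone numbered 1222, of which 15 lay on scaffolds, and these raise only the share of Day 12- 8. The scaffold counts therefore leave open whether background adds to the sharing. Of the 3705 sites that Day 12- 8 shared with day 0, 62.3% were also called at day 8 or day 12, and 37.5% were called at none of days 4, 8 and 12.

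Chromosome 4 held 7.15, 7.04, 7.61 and 9.88% of sites at days 0, 4, 8 and 12, and 11.2, 9.50 and 11.7% in the libraries titled Day 12- 4, Day 12- 8 and Day 12- 12. It was picked out after the values of all chromosomes were seen, and chromosome 5 had a similar course, at 8.18, 9.20, 8.71 and 9.84%, then 9.74, 9.14 and 11.4%. Of the sites on chromosome 4 called at both day 4 and day 8, 32.2% (30.03 to 34.38) were also called in the library titled Day 12- 4, against 26.3% (25.7 to 26.8) over all chromosomes. Chromosome 11 had the next highest share, 28.9%. For the library titled Day 12- 8 the value was 9.70% (8.37 to 11.2) on chromosome 4 and 10.2% over all chromosomes. For Day 12- 12 it was 56.5% (54.2 to 58.8) against 52.0%, below 57.9% on chromosome 17 and 57.4% on chromosome 11.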
